A study of Mus musculus with 2 samples.

How the data were processed

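Single-cell RNA-seq libraries (10x 3' v2) were made from CD326-sorted epithelium of the growth region of the mouse incisor, 1 control library and 1 library taken 3 days after 5-fluorouracil. Each pooled 5 male C57BL/6J mice of 8 to 12 weeks, and 3000 cells were targeted for each. The matrices hold raw UMI counts per gene and barcode, deposited by the authors as made by Cell Ranger, whose version and annotation release are not given in the sources used here. The submitters' processing notes name the builds mm10 and GRCm38. The cell table holds, per the file headers, an S score and a G2M score per cell, centred on 0, and how the authors made each score is not given in the sources used here. It also gives the authors' library, quality flag, class, population, phase, closest population of cycling cells and, for 431 control cells, a pseudotime rank. The authors also deposited mean expression per population, which was checked to equal the mean over cells of counts per 10000, with a largest deviation of 0.0004 over 30 population means. It was not used further.

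The pooled and per-library matrices were checked against each other over 27877 gene symbols, and 0 entries differed. Of 27998 genes, 27722 were found by Ensembl ID in GENCODE vM21 (GRCm38), which gave the coordinates, and 121 gene IDs shared a symbol with another. No columns of samples outside the series were found (0). The authors' quality flag matched a minimum of 1000 genes and a mitochondrial share under 10% for all 8594 barcodes: 776 failed, 761 of them with under 1000 genes. The 6693 cells that the authors retained as epithelium were analysed. Barcodes that failed, and those excluded as immune or mesenchymal, were used only where they are named.

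Shares of cells were given with exact Clopper-Pearson 95% intervals, and ratios of shares with log-scale intervals. For genes, UMIs were summed over the cells of a library, or of a population with at least 100 cells in both libraries, and scaled to CPM. Ratios are injured over control, with exact conditional binomial 95% intervals. Genes with at least 50 CPM in either library were considered, and a 2-fold difference in either direction was counted. Where a library had 0 counts, the fold is a bound against 3 counts. Cells and UMIs are not replicates of a condition, so these intervals say nothing about the spread between animals or libraries.

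The genes named in the text followed a rule fixed in advance. It took the 12 highest and 12 lowest median within-population ratios among genes with the same direction in all compared populations and at least 50 CPM over all retained cells, then the 3 highest and 3 lowest further genes of each population. It also took list members past 2-fold (up to 4 a list, or the 2 largest), up to 3 leading markers of each population, and Epcam, Cdkn1a, Mki67, Notch1, Sox2, Amelx and Tyms. Mitochondrial, ribosomal protein and haemoglobin genes were not named singly under the parts on ratios across and within populations. The results of 2 genes that the rule names are not reported here.

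Gene lists of cell types and programmes were compared through members with at least 10 CPM in either library. The median log2 ratio was placed among 10000 random lists of the same size, matched on expression in 20 bins, as a description and not a test. Cells positive for the S-phase or G2/M list had at least 2 UMIs of it after each cell was thinned to 2000 UMIs, which left out 148 control and 451 injured cells. Values without thinning were also computed. The procedures were tested on simulated Poisson counts with the depths of these libraries. The simulation held no spread between cells or libraries, so its shares cover counting error only and are not error rates of the data. Over all cells, 100 of 100 genes simulated at 3-fold and 0 of 100 simulated at 1.5-fold passed the 2-fold limit. In OEE_IEE, the comparison with the fewest UMIs, 97 of 100 passed at 3-fold, 8 of 100 at 1.5-fold and 37 of 3067 unchanged genes. A planted list of 12 genes at 1.5-fold lay at percentile 100 in each of the 8 comparisons.

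The alternatives were TMM factors, DESeq2 size factors, other minimum CPM values, mean CPM per cell, totals without mitochondrial and ribosomal protein genes, every barcode, cells above the 10th percentile of depth (2035 UMIs), medians within populations, other thinning depths and UMI limits, doublets left out, and own clusters. Own clusters were made with the Leiden method at resolution 1 on 2000 variable genes without the phase lists, 30 components and 15 neighbours. The automatic threshold of Scrublet, as implemented in scanpy, marked 0 doublets. The highest scores at an expected rate of 0.8% per 1000 barcodes were therefore left out instead, which took 34 control and 163 injured retained cells. Genes whose control CPM in AMB_prox and AMB_dist, or in excluded barcodes, was at least 5 times that in other retained cells were left out in a further alternative, which removed 1018 genes. Tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scanpy 1.11.5, leidenalg 0.10.2, matplotlib 3.10.9, R 4.3.3, edgeR 4.0.16 and DESeq2 1.42.0.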

Results

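Single-cell RNA-seq was made from the epithelium of the growth region of the mouse incisor, a tooth that keeps growing and renews its enamel-forming epithelium throughout life. Cells were sorted for the epithelial surface protein EPCAM (CD326). The control library came from untreated animals and the injured library from animals taken 3 days after 5-fluorouracil, a pyrimidine analogue that blocks thymidylate synthase and is toxic to dividing cells. Each library pooled 5 male wild-type mice, so each condition had 1 library, and condition and library were the same factor. No test between conditions was therefore possible, and no p-value is given. Values are given with 95% intervals that cover counting error only: exact Clopper-Pearson intervals for shares, log-scale intervals for ratios of shares and exact conditional binomial intervals for ratios of CPM, the UMIs of a gene scaled by all UMIs of the same cells. The question was how the epithelial cell populations, and the genes expressed in them, differed between homeostasis and early injury.

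The control library held 3600 barcodes with 14231878 UMIs and a median of 3174.5 UMIs per barcode. The injured library held 4994 barcodes with 22626430 UMIs and a median of 3628. The authors' cell annotation retained 2349 control and 4344 injured cells as epithelium, with medians of 3330 and 4052.5 UMIs and of 1618 and 1903.5 genes. Those cells carried 9507749 and 21010562 UMIs. Ribosomal protein genes took a median of 21.4% of a control cell's UMIs and 17.5% of an injured cell's.

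Immune and mesenchymal barcodes, which the authors set aside, made up a larger part of the control than of the injured library. They were 824 of the 3173 control barcodes that passed the quality filter (26.0%, interval 24.5 to 27.5) and 301 of 4645 injured ones (6.48%, interval 5.79 to 7.23). The pan-leukocyte gene Ptprc was seen in 46.8% of these control barcodes and 32.2% of the injured ones, against 2.68% and 0.622% of retained cells. Their 10-gene immune list summed to 35854 CPM in the control and 33540 CPM in the injured library, and to 1321 and 331 CPM in retained cells. The mesenchymal list, with Col1a1 and Lum among its 10 genes, summed to 1223 and 1327 CPM there and to 368 and 558 CPM in retained cells. Both libraries had passed the same CD326 sort.

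Differentiating enamel-forming populations were far less frequent in the injured library, and class 1, the class that holds the cycling populations M_G1, S and G2_M, was more frequent. Class 2, made of pre_AMB, AMB_prox and AMB_dist, took 18.3% of control cells (431 cells, interval 16.8 to 19.97) and 1.34% of injured cells (58 cells, interval 1.02 to 1.72), a ratio of 0.0728 (0.0556 to 0.0953). Class 1 took 36.7% and 57.1%, a ratio of 1.56 (1.47 to 1.65). Class 3, the other 9 populations, took 44.96% and 41.5%, a ratio of 0.924. The population names are the authors', and the sources used here do not spell them out.

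Within class 2, pre_AMB fell from 338 control cells (14.4%) to 53 injured cells (1.22%), AMB_prox from 67 cells to 2, and AMB_dist from 26 cells to 3. In class 3, upper_IEE was 7.49% of control and 0.506% of injured cells, a ratio of 0.0676, and SI was 4.26% and 1.08%, a ratio of 0.254. OEE_2 was 5.07% and 14.1%, a ratio of 2.78 (2.30 to 3.36). DEEx was 7.36% and 9.09%, a ratio of 1.23 (1.04 to 1.47). OEE_IEE had a ratio of 0.591, OEE_1 of 0.479 and OSR of 0.808. The intervals of ISR_SI (ratio 0.951) and VEE (ratio 1.16) held 1, so a difference was not detectable at this depth. With class 1 left out of the denominator, OEE_2 made up 8.00% and 32.8%, DEEx 11.6% and 21.2%, and pre_AMB 22.7% and 2.85%. The ratios of ISR_SI (1.40, 1.10 to 1.79) and VEE (1.72, 1.31 to 2.25) were then above 1, and the intervals of OEE_IEE (0.873), OEE_1 (0.707) and OSR (1.19) held 1.

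**Figure D1:**
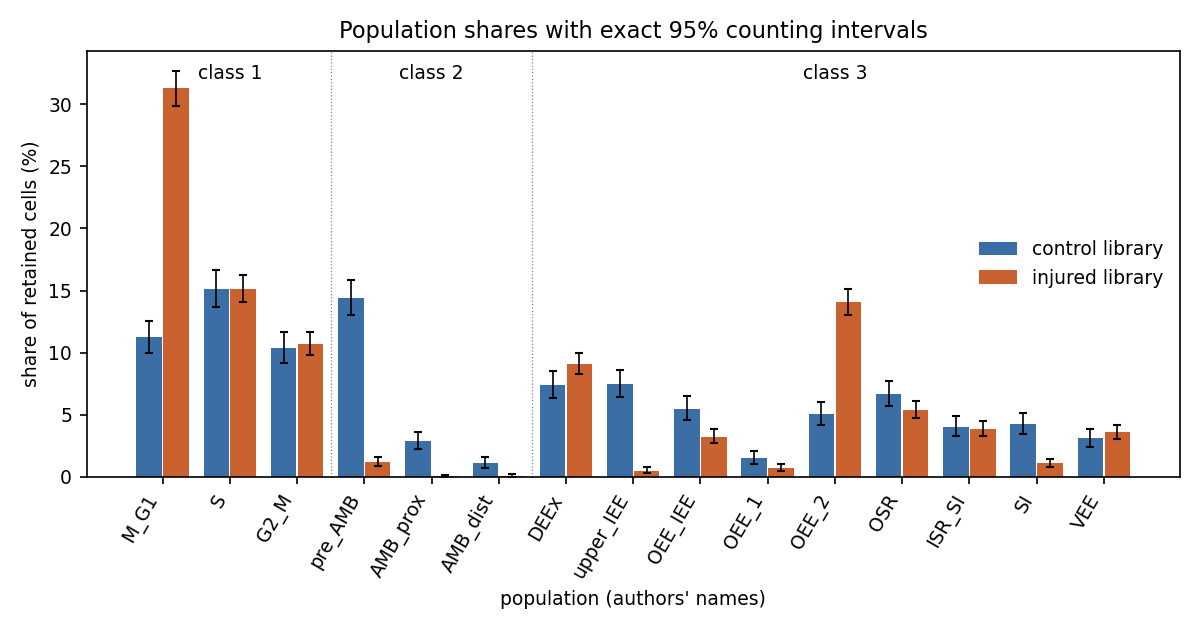
Share of retained cells (vertical axis, %) in each of the authors' 15 populations (horizontal axis) in the control library (blue) and the injured library (orange), with exact 95% counting intervals as error bars. M_G1 stands at 11.2% and 31.3% and pre_AMB at 14.4% and 1.22%.

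Inside class 1, M_G1 was 11.2% of control and 31.3% of injured cells, a ratio of 2.78 (2.46 to 3.14), while S was 15.1% in both and G2_M was 10.3% and 10.7%. The genes that separate these populations also differed inside them. By the authors' own phase calls, 6.44% of control and 39.2% of injured M_G1 cells were in S phase, so M_G1 did not hold the same mix of cells in the libraries and its ratio depends on where it ends. Epcam, the gene for the sorted protein, was at 766 CPM in control and 489 CPM in injured cells, and whether the sort selected alike in the libraries was not tested. Clustering without the phase genes parted the libraries in several clusters: the largest held 832 control and 2 injured cells, and only 34.3% of the cells in the cluster matched to OEE_IEE were OEE_IEE cells. Its ratios for DEEx (0.0103), OEE_IEE (9.97) and class 3 (1.16) went the other way but do not count the same populations.

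Class 1 cells resembled different non-cycling populations in the libraries. In the authors' assignment of each class 1 cell to its closest class 2 or class 3 population, 12.4% of control and 44.5% of injured cells were closest to DEEx, a ratio of 3.59 (2.99 to 4.31). Cells closest to pre_AMB were 34.7% and 7.74%, a ratio of 0.223 (0.189 to 0.263). Cells closest to upper_IEE were 30.9% and 27.8%, and their interval held 1. The share closest to DEEx was higher in M_G1 (10.6% and 42.0%), S (10.4% and 49.7%) and G2_M (17.3% and 44.4%) alike.

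Leading marker genes, taken only from the cell type lists at 50 CPM or more, described what the population names hold. In the control library, AMB_dist was led by Amtn, Ambn and Enam, genes of enamel matrix and maturation proteins, with Enam at 29847 CPM, 36.4 times its level in other retained cells. AMB_prox was led by the dentin sialophosphoprotein gene Dspp, at 54.4 times other cells, and by the haemoglobin genes Hba-a1 (54.1 times, 84 UMIs) and Hba-a2 (41.0 times, 40 UMIs), and held Enam at 17769 CPM and the enamel protease gene Mmp20 at 1615 CPM. Col22a1, Kif5c and Vwde led pre_AMB, at 4.93, 3.54 and 3.44 times other cells. Odam, from 22 UMIs, Cygb and Alpl led SI, with Cygb and Alpl each 14.0 times higher. Th, at 62.5 times, and Krt15, at 44.4 times, led VEE. Lum, Slco4a1 and Krt15 led OEE_2, at 11.3, 10.6 and 9.61 times. Ntrk2 and Grp led OEE_1, at 15.8 and 14.8 times. Cldn10 and Grp led OEE_IEE, at 6.21 and 5.84 times. Dcn, Lum and Sfrp5 led DEEx, at 5.80, 4.54 and 3.51 times. Tagln and Acta2 led OSR, at 17.9 and 8.82 times, and Postn, from 29 UMIs, Tagln and Col1a2 led ISR_SI, at 124, 9.80 and 7.24 times. Fam19a4, Fgf9 and Cldn10 led upper_IEE, at 3.38, 2.16 and 1.84 times. The cell type lists hold no S-phase or G2/M list gene, and their leading markers in the class 1 populations stood out little. Vat1l was 1.91 times higher in M_G1 and 1.35 times higher in S than in other cells. Sfrp5 was 1.47 times higher in G2_M than in other cells.

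Sfrp5, Crtac1 and Lgals1 were among the genes higher in every compared population of the injured library, and genes of enamel matrix and of antigen presentation were lower in each of them. The 7 populations with at least 100 cells in both libraries were compared: M_G1, S, G2_M, DEEx, OEE_IEE, OEE_2 and OSR. Clustering set some of their cells apart by library, so these ratios do not compare like clusters: the cluster matched to DEEx held 210 control and 4 injured cells, and 2 clusters matched to G2_M held 322 and 5, and 33 and 423. Crtac1, which encodes a secreted matrix protein, had a median 4.81-fold higher CPM over these populations. Sfrp5, a secreted WNT inhibitor expressed in the labial cervical loop, was 4.64-fold higher, with log2 ratios from 1.10 to 2.77. Igfbp3, which binds insulin-like growth factors, was 3.68-fold higher, Lgals1 (galectin 1) 3.65-fold and Nppc (C-type natriuretic peptide) 3.64-fold. The other genes named by the same rule were Cdc42ep3 (2.76-fold), the thymidine kinase gene Tk1 (2.72), Ddit4l (2.71), the importin gene Kpna2 (2.69), Anxa1 (2.66), Itm2a (2.61) and Lmo1 (2.57). Control Tk1 and Kpna2 stood at 51.4 and 62.5 CPM in excluded barcodes, above medians of 29.5 and 17.9 CPM in these populations. That level was no common background, as control OEE_2 stood at 12.6 and 3.14 CPM. Of the control excluded barcodes, 9.85% had at least 5 G2/M list UMIs after thinning. These levels therefore cannot decide whether either gene was expressed outside class 1.

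Sfrp5 (ENSMUSG00000018822) lies on chromosome 19 at 42197971 to 42202252 on the minus strand (GRCm38). Over all retained cells it had 1577 control and 15278 injured UMIs, which is 166 and 727 CPM and a ratio of 4.38 (4.16 to 4.62). Among the excluded barcodes it stood at 47.7 and 204 CPM, below the median of the compared populations (226 and 1047 CPM) but near OSR (51.6 and 261 CPM), where its ratio is not read as expression. Lgals1, Igfbp3 and Anxa1 were different: their control levels in excluded barcodes, 746, 160 and 53.4 CPM, were above the median of the compared populations, 197, 69.4 and 23.0 CPM. Crtac1 (chromosome 19, 42283035 to 42431783) was at 30.6 CPM in control and 78.7 CPM in injured retained cells. It lies near Sfrp5, and why both were higher was not tested.

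Enam, Amelx and Ambn, which encode the main enamel matrix proteins, and Calb1, a calcium-binding protein of ameloblasts, were lower in all 7 populations of the injured library, by medians of 38.2, 15.4, 10.6 and 16.1-fold. H2-Ab1, H2-Aa, H2-Eb1 and Cd74, genes of MHC class II antigen presentation, were lower by 8.29, 8.16, 7.17 and 6.90-fold, and the immune genes Ctss and Ccl4 by 5.202 and 4.44-fold. Igfbpl1 was lower by 5.79-fold.

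Levels of the enamel and immune genes differed little between control populations, from 1.18-fold for H2-Aa to 2.23-fold for Calb1 between the highest and the lowest, and were also found in barcodes of other cell types. Amelx (chromosome X, 169176114 to 169187200) ran from 461 CPM in G2_M to 573 CPM in OEE_IEE in the control library, and was 585 CPM in the excluded immune and mesenchymal barcodes, against 97943 CPM in AMB_prox and AMB_dist together. In the injured library it ran from 26.3 to 45.7 CPM and was 44.0 CPM in the excluded barcodes. Cd74 ran from 473 to 637 CPM in the control populations and from 63.7 to 109 CPM in the injured ones, against 18977 and 11927 CPM in excluded barcodes. Igfbpl1 varied more between control populations, from 28.3 to 375 CPM, and was at 72.2 CPM in the excluded barcodes.

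**Figure D2:**
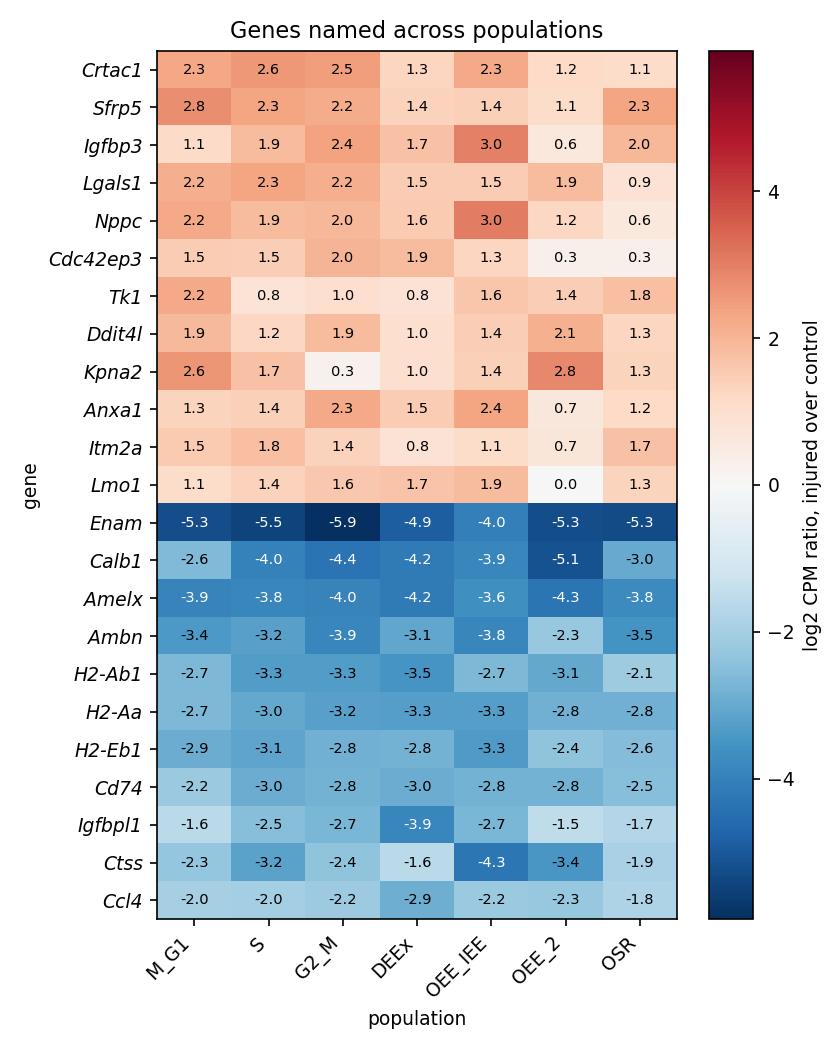
Log2 CPM ratios (injured over control, colour and printed value) of the 12 highest and 11 of the lowest genes across populations (vertical axis) in the 7 compared populations (horizontal axis). Enam has the lowest values, down to -5.92 in G2_M, and Sfrp5 reaches 2.77 in M_G1.

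**Figure D3:**
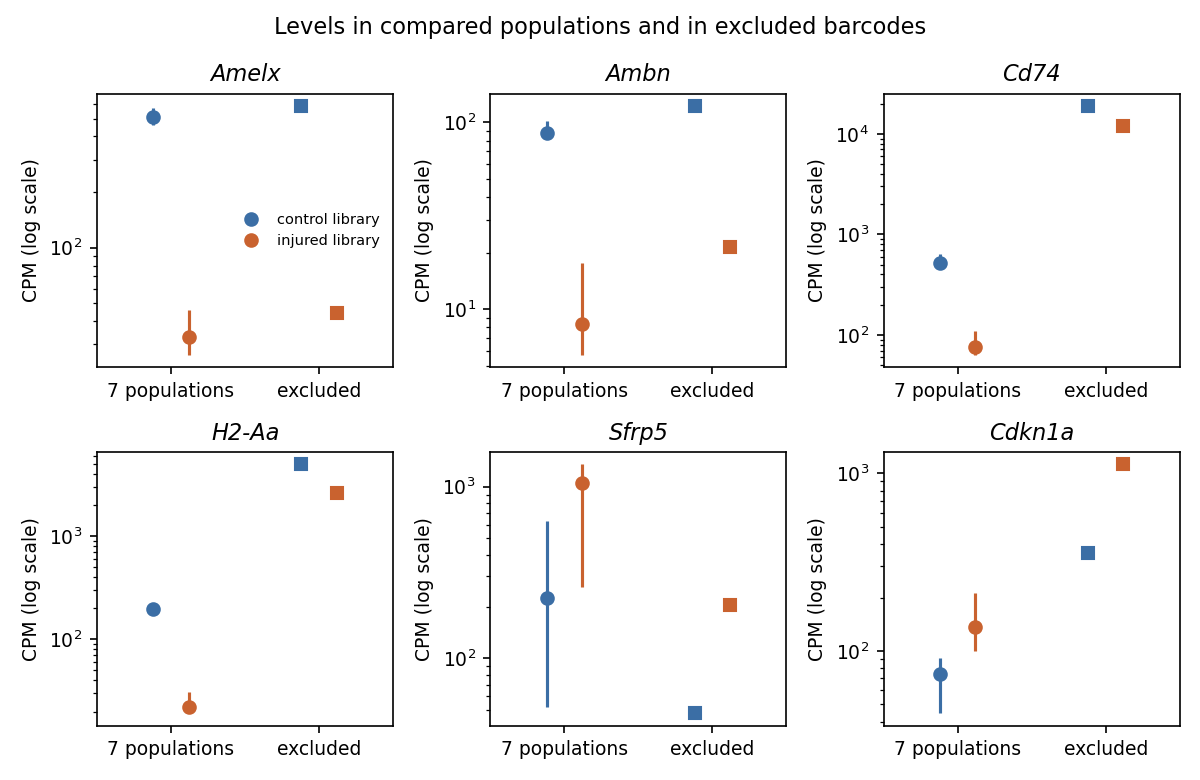
CPM on a log axis of Amelx, Ambn, Cd74, H2-Aa, Sfrp5 and Cdkn1a in the control (blue) and injured (orange) libraries; circles are medians over the 7 compared populations, lines their range, and squares the excluded immune and mesenchymal barcodes. Control Amelx in excluded barcodes (585 CPM) lies at the level of the compared populations (median 512 CPM).

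Of 3477 genes considered, 31 were higher and 40 lower in the same direction in all 7 populations with a median of at least 2-fold. Leaving out 1018 genes whose control level was at least 5 times higher in AMB_prox and AMB_dist or in excluded barcodes than in other retained cells left 29 higher and 23 lower. As these sources were defined in the control library only, this hardly checks the higher genes. With mitochondrial and ribosomal protein genes out of the totals the counts were 20 and 44. In single populations the counts of genes higher and lower by at least 2-fold were 133 and 113 in M_G1, 43 and 95 in S, 73 and 86 in G2_M, 87 and 75 in DEEx, 188 and 135 in OEE_IEE, 113 and 89 in OEE_2, and 114 and 78 in OSR. TMM scaling shifted the log2 ratios of M_G1 by 0.10 (DESeq2 size factors by 0.12 there, 0.11 in S and -0.11 in OEE_IEE) and gave 181 and 89 there, and 61 and 84 in S. Taking mitochondrial and ribosomal protein genes out of the totals gave 141 and 170 in M_G1, 38 and 148 in S, 72 and 113 in G2_M, 94 and 153 in DEEx, 216 and 272 in OEE_IEE, 140 and 130 in OEE_2, and 122 and 144 in OSR.

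In M_G1 the highest ratios after those genes, among genes of at least 50 CPM in either library of the population, were those of Gins2, Rrm2 and Hist1h1b. Gins2, of the replicative helicase, was 12.9-fold higher (5.91 to 35.4), from 6 to 646 UMIs, and Rrm2, a subunit of ribonucleotide reductase, was 11.2-fold higher (8.02 to 16.1). The linker histone gene Hist1h1b was 9.38-fold higher (4.52 to 23.4). In S, Hist1h2bc was 4.31-fold, Igfbp2 3.57-fold and the retinaldehyde dehydrogenase gene Aldh1a3 3.53-fold higher. In G2_M, Golga7b was 17.7-fold higher (7.42 to 55.2, from 5 control UMIs), Lor 7.42-fold and Sparcl1 5.79-fold. Fam19a1 was the lowest of the remaining genes in all of M_G1, S and G2_M, by 6.85, 8.17 and 11.0-fold. The chemokine gene Cxcl2 (5.09-fold) and the heat shock gene Hspa1a (5.03-fold) were lower in M_G1, Iqgap2 (6.05-fold) and Ank2 (6.00-fold) in S, and Vwde (7.18-fold) and Pla2r1 (6.22-fold) in G2_M.

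In DEEx, Epyc had no control UMI and 86 injured UMIs, at least 14.3-fold higher against a floor of 3 counts. Car2, a carbonic anhydrase, was 7.07-fold and Pthlh, a parathyroid hormone-related peptide, 5.79-fold higher, while Cd14, Cxcl2 and Cttnbp2 were lower by 6.19, 5.46 and 5.41-fold. In OEE_2, Birc5, a gene of the chromosomal passenger complex, was 9.42-fold higher (2.53 to 79.0, from 2 control UMIs), Tnfrsf11b (osteoprotegerin) 6.66-fold and 1600020E01Rik 5.65-fold. The 90 injured UMIs of Birc5 lay in 82 of 611 cells, with at most 3 in a cell, and as a G2/M list gene it is not read as expression in OEE_2. Alpl, which encodes tissue-nonspecific alkaline phosphatase, was 10.8-fold lower in OEE_2 (control 107 CPM, injured 9.87 CPM), Gpx3 7.20-fold and Cntfr 6.82-fold. In OSR, Cst6 was 22.7-fold higher but from 1 control UMI (3.81 to 924), Nupr1 10.5-fold and Dpysl3 9.36-fold. OSR of the injured library also held endothelial markers and the pericyte marker Rgs5, chosen after their values were seen: Plvap had 0 control and 22 injured UMIs, Pecam1 1 and 13, Emcn 0 and 7, and Rgs5 2 and 29. Other genes of the pericyte and smooth muscle list did not follow Rgs5: Cspg4 was at 6.73 and 6.00 CPM, Notch3 at 4.49 and 4.50, and Tagln at 707 and 475. Mcam was at 15.7 and 22.5 CPM. In how many OSR cells these UMIs lay was not counted. Aif1, a macrophage gene, was 4.92-fold lower there, Enpp2 4.49-fold and Gm42726 3.93-fold.

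In OEE_IEE the lowest genes were Tpsb2, Cma1 and Cpa3, which encode mast cell proteases. They had 119, 68 and 66 control UMIs and no injured UMI, at least 34.4, 19.7 and 19.1-fold lower against a floor of 3 counts. A single control cell of 129 held 114, 67 and 66 of those UMIs, so these ratios rest on 1 cell. Ino80c was 11.0-fold higher in OEE_IEE (2.64 to 97.0) and Serpinb5 7.30-fold (2.15 to 38.5). Rhox5, with no control UMI and 22 injured UMIs in 7 cells, was at least 8.46-fold higher.

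Over all retained cells, ratios also move with population shares. Of 3500 genes, 43 were higher and 83 lower by at least 2-fold. TMM scaling gave 58 and 68, and DESeq2 size factors, which shifted all log2 ratios by 0.10, gave 67 and 68. Without the 1018 genes of other sources the counts were 41 and 49. Medians within populations gave 46 and 52. The median log2 ratio of all genes was 0.12. Enam was at 1281 CPM in control and 16.6 CPM in injured cells, a 77.1-fold lower level, and Amelx at 6249 and 254 CPM, 24.6-fold lower.

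Several genes of injury response, proliferation and stem cells were reported whatever their ratio. Cdkn1a, the p53-induced cyclin-dependent kinase inhibitor p21, was at 153 and 170 CPM over all cells (ratio 1.11, 1.05 to 1.18), but within populations its median was 2.16-fold higher, from 1.38-fold in OEE_2, where the interval held 1, to 3.04-fold in OSR. It was at 1093 CPM in control AMB_prox and AMB_dist, which were almost absent from the injured library. Its level in excluded barcodes, at 357 and 1122 CPM, was above the 7 compared populations, which reached 91.2 and 211 CPM. Mki67, a proliferation marker, was at 115 and 132 CPM (ratio 1.14), and at 222 and 166 CPM in class 1 (ratio 0.750, 0.696 to 0.808). Tyms, which encodes thymidylate synthase, was at 127 and 234 CPM (ratio 1.84, 1.73 to 1.96), with ratios of 2.68 in M_G1, 1.14 in S and 1.80 in G2_M. Notch1, a receptor of the stratum intermedium, was at 30.0 and 23.1 CPM (ratio 0.770), with a ratio of 0.545 (0.431 to 0.689) in class 3, but at 171 and 159 CPM in SI, whose share fell. Sox2, a dental epithelial stem cell factor, was at 12.9 and 13.4 CPM, and a difference was not detectable at this depth (ratio 1.04, 0.837 to 1.29). Epcam had a ratio of 0.639 over all cells, 0.431 in M_G1 and 0.899 in OEE_IEE.

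Gene lists fixed before the data were examined were compared by their median log2 CPM ratio over all retained cells. Each median is given with its percentile among 10000 random lists of the same size and expression, as a description of these libraries. All 20 measured S-phase genes were higher (median 0.94, percentile 100), 9 of them by at least 2-fold, led by Ccne1 (3.85-fold), Rrm2 (3.10-fold), Cdc6 (2.74-fold, but a median log2 of 0.80 within populations) and Ccne2 (2.34-fold). All 11 measured genes of pyrimidine metabolism and 5-fluorouracil response were higher (0.86, percentile 100), with Tk1 2.59-fold higher. Ribosome biogenesis was higher in 13 of 14 genes (0.55, percentile 99.99), with Ncl 1.65-fold and Nolc1 1.61-fold higher; their median log2 ratios within populations were 0.05 and 0.36. All 20 G2/M genes were higher (0.34, percentile 98.8), none by 2-fold, with Birc5 at 1.82-fold and Cdk1 at 1.67-fold. With a minimum of 50 CPM this median fell inside the random range, and it was -0.34 in class 1 and 0.79 in class 3.

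Genes of enamel matrix and mineral were lower in all 6 measured members (-4.86, percentile 0), among them Mmp20 (75.0-fold) and Dspp (34.4-fold). The secretory ameloblast list was lower in 4 of 4 (-5.42) and the pre-ameloblast list in 9 of 9 (-1.33), both at percentile 0, with Kif5c 3.72-fold and Vwde 3.64-fold lower. Immune genes were lower in 9 of 9 (-1.72, percentile 0), with Cd52 (5.76-fold), Tyrobp (4.06-fold) and C1qa (3.29-fold) beside Cd74. Immediate-early and dissociation genes were lower in 15 of 15 (-0.51, percentile 0), with Hspa1a 3.23-fold lower, but not in every population: the median was 0.74 in OEE_IEE (percentile 100), where 13 of 15 were higher, and the within-population median was -0.14 (percentile 1.18). All 7 Notch genes were lower (-0.38, percentile 1.78), with Jag1 2.26-fold lower; the within-population median was -0.08 and inside the random range.

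The dental epithelial progenitor list was higher in 6 of 8 genes (0.34, percentile 96.6), led by Sfrp5, and its median lay at percentile 98.7 or above in each of the 7 populations, from 0.36 in S to 1.68 in G2_M. The mesenchymal list was higher in 4 of 5 (0.67, percentile 99.9), with Lum and Col1a1 each 2.13-fold higher; Lum was also a leading gene of OEE_2 and DEEx, and these ratios reversed when every barcode was counted. Glycolysis and hypoxia genes were higher in 6 of 10 (0.37, percentile 98.7), although the named members Ndrg1 (3.22-fold) and Hk2 (2.03-fold) were lower, with median log2 ratios within populations of -0.23 and -0.78. The p53 target list had a median of 0.23 (percentile 93.2; 11 of 16 higher), with Ddit4l 2.70-fold and Pmaip1 2.14-fold higher and Btg2 2.28-fold lower. Within the 7 populations its medians ran from 0.32 to 0.60, at percentiles from 98.1 to 99.97. With each gene's median over populations, the list stood at 0.27 (percentile 97.06), inside the random range.

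Other lists lay inside the central 95% of random lists. The unfolded protein and integrated stress list had a median of 0.21 (percentile 77.9), with Sdf2l1 1.58-fold and Hspa5 1.42-fold higher. WNT genes had 0.14 (80.7), with Sfrp5 and Lef1 (2.70-fold) higher and Wnt6 (3.42-fold) lower. Hedgehog genes had 0.01 (55.1), with Gas1 2.04-fold lower. BMP and activin genes had -0.03 (26.7), with Fst 2.03-fold higher and Smad6 2.53-fold lower, and FGF and MAPK genes -0.03 (27.5), with Fgf9 1.81-fold and Spry2 1.54-fold lower. YAP targets had -0.23 (12.5), with Cyr61 1.65-fold higher and Axl 1.73-fold lower. The epithelial list had -0.01 (20.7), with Krt8 at a ratio of 0.665. TMM scaling adds 0.08 to each median and to its random range alike, so it moves no percentile, but it makes the BMP, FGF and epithelial medians positive. Stratum intermedium genes had -0.20 (14.6), with Alpl 2.56-fold lower and Gnrh1 2.17-fold higher. Stellate reticulum and outer epithelium genes had -0.16 (18.0), with Vat1l 4.33-fold lower and Ntrk2 2.27-fold higher (a median log2 of 2.03 within populations). Fewer than 3 members were measured for the interferon (Ifi27l2a 1.16-fold higher, Bst2 1.11-fold lower), wound keratinocyte (Krt17, ratio 1.05), erythroid (Hba-a1 16.4-fold lower), endothelial (Egfl7, ratio 0.861) and pericyte and smooth muscle (Tagln, ratio 0.731; Mcam, 1.30) lists, so they have no median.

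**Figure D4:**
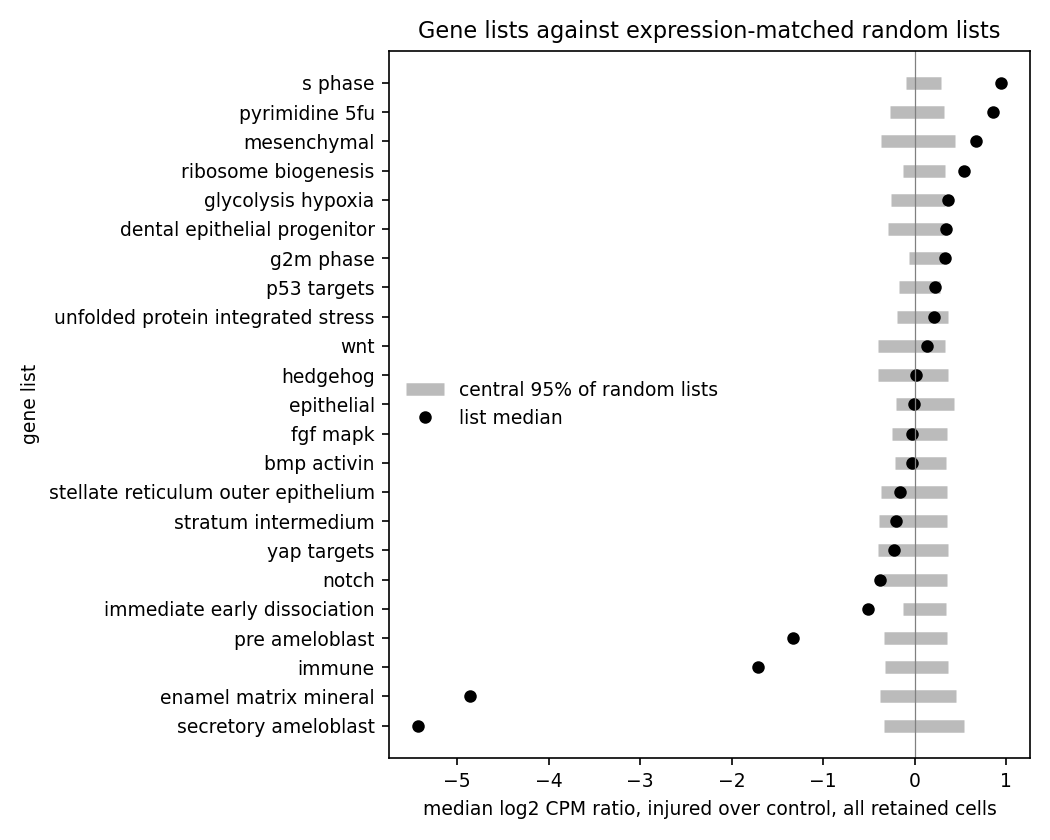
Median log2 CPM ratio over all retained cells (black points, injured over control) of each gene list with at least 3 measured members, beside the central 95% of 10000 expression-matched random lists (grey bars). S-phase genes stand highest at 0.94 and secretory ameloblast genes lowest at -5.42.

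Cells carrying S-phase transcripts were more frequent in the injured library at equal depth. Each cell was thinned to 2000 UMIs, leaving out 148 control and 451 injured cells below that depth, and a cell with at least 2 UMIs of a list was counted as positive. S-phase positive cells were 52.5% of control and 74.6% of injured cells, a ratio of 1.42 (1.36 to 1.49). Class 1 gave 74.2% and 87.2% (ratio 1.18, 1.13 to 1.23), class 3 gave 42.5% and 54.1% (1.27), and M_G1 gave 44.4% and 83.6% (1.88, 1.63 to 2.17). Without thinning the shares over all cells were 66.3% and 80.7%.

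G2/M positive cells were 36.8% and 59.2% of all cells (ratio 1.61, 1.52 to 1.71), and 46.7% and 68.6% without thinning. In class 1 the shares were 78.5% and 80.4%, and a difference was not detectable at this depth (ratio 1.02, 0.984 to 1.07). In class 3 they were 12.0% and 24.0% (ratio 2.00, 1.65 to 2.43). VEE, where the authors called 0 of 73 control and 1 of 157 injured cells G2/M, serves as the background: its positive shares were 2.99% and 20.8% at median depths of 3175 and 2710 UMIs. The injured shares of the class 3 populations DEEx, OEE_IEE, OEE_2, OSR, ISR_SI and SI lay between 20% and 26.8%, near that of VEE. The comparison cannot show whether VEE cells made these transcripts themselves. The shares are therefore read neither as expression nor as RNA from other cells. OEE_1 (30%, 6 of 20 cells) and upper_IEE (38.1%, 8 of 21 cells) lay higher. In the control library the 8 other class 3 populations all lay above VEE, from 4.26% in SI to 19.4% in DEEx, so VEE gave no shared background there. S-phase positive cells were 11.9% and 35.4% of VEE cells, against 25.8% and 45.9% of OEE_2 cells and 50.3% and 67.9% of DEEx cells. By the authors' phase calls, G2/M cells were 1.52% of control and 0.831% of injured class 3 cells.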

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

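The tests on deeper injured cells, on more class 1 cells in S phase, on Enam, Ambn and Calb1 in excluded barcodes and on doublets by the highest Scrublet scores were chosen only after the result was seen. The G2/M list had a median log2 ratio of -0.34 in class 1 and 0.79 in class 3, a difference between classes that was not tested. Within the class 1 populations its medians were 0.14 in M_G1, 0.46 in S and 0.07 in G2_M, so the class 1 value goes with the shares of these populations. A signal also appeared in barcodes that failed the quality filter: the glial and neural crest list summed to 19.2 CPM in the control (13 UMIs) and 54.7 CPM in the injured library (30 UMIs).

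Enamel and immune genes were lower in all 7 compared populations of the injured library. Lower expression inside these cells is argued against for Amelx, which was lower by 13.3-fold in excluded barcodes and by a median of 15.4-fold in the populations, a ratio of 0.861, and for Calb1 (ratio 1.67, 0.648 to 6.16) and Enam (0.831 with no injured UMI set at 3 counts, interval from 0.672), but not for Ambn (5.69 and 10.6-fold, ratio 0.535, 0.352 to 0.851). Free ameloblast RNA in the control droplets may account for the enamel part. Control Amelx in excluded barcodes was 1.14 times the median of the populations (Calb1 1.15, Ambn 1.39 and Enam 1.60 times). However, AMB_prox and AMB_dist together had 0.215 Enam and 0.0971 Ambn UMIs per Amelx UMI, against at most 0.129 and at least 0.143 in the populations. The pooled Ambn value does not stand for each of them. AMB_dist alone had 3627 Ambn, 4503 Enam and 19931 Amelx UMIs. Its Ambn per Amelx UMI lay within the range of the populations (0.143 to 0.220), while its Enam per Amelx UMI lay above theirs. Free immune RNA may account for the antigen presentation part, since Cd74 per Lyz2 UMI ran only from 1.66 to 2.32 over the control populations, highest over lowest 1.39, but excluded barcodes had 3.17 (3.12 to 3.21). A difference inside cells caused by the injury stays open there, for Ambn and for Igfbpl1 (2.96-fold in excluded barcodes and 5.79-fold in the populations). In both libraries, though, Ambn was higher in excluded barcodes than the median of the populations (control 1.39 and injured 2.59 times).

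M_G1 had a larger share and more S-phase positive cells in the injured library. Depth alone is argued against, because at equal depth the ratio of positive M_G1 cells was 1.88 (1.63 to 2.17). Another boundary between M_G1 and S is a candidate explanation: control profiles assigned 2.59% of held-out control and 40.5% of injured M_G1 cells to S, 37.9 percentage points apart. They also assigned more injured than control cells to S in G2_M (3.28% and 13.2%) and in S (75.9% and 90.3%). The shift is thus not particular to M_G1. More class 1 cells in S phase is another candidate, since the ratio over class 1, which no boundary inside it moves, was 1.18 (1.13 to 1.23). Free RNA from S-phase cells was not tested for this pattern. It stays open, as VEE also had more positive cells (11.9% and 35.4%), though fewer than M_G1 (44.4% and 83.6%).

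More class 3 cells were positive for the G2/M list in the injured library. Without the highest Scrublet scores the ratio was 1.97 (1.62 to 2.40). That step removed 163 injured retained cells of all classes, while 337 injured class 3 cells were positive. Removing so few cells could hardly bring the interval to 1, so doublets stay open. Free RNA from cycling cells and more dividing class 3 cells cannot be told apart, as the excess over Poisson counts was 2.12 percentage points higher in the injured library, between the limits set for either reading. Positive VEE cells were 2.99% and 20.8%, with 0 of 73 and 1 of 157 called G2/M. Called G2/M cells of class 3 were 1.52% and 0.831%, a ratio of 0.549 (0.272 to 1.11) whose interval held 1. The authors' median G2M score was lower in the injured library in each class 3 population (OEE_2 -0.307 and -0.413). How that score was made is not given, so these calls favour neither reading. Cells with at least 5 UMIs were too few to decide (6 and 20), with a ratio of 2.26 (0.910 to 5.599) whose interval held 1.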

How the results depend on the processing

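Leaving out the highest Scrublet scores, leaving out genes of other sources and leaving out M_G1 were chosen only after the result was seen; other alternatives were fixed before the data were examined. With 1 library per condition, none of them speaks to the spread between libraries. Of 52 shares of populations and classes, 38 stayed within their counting interval, but only 12 of 30 ratios of positive cells did. Of 526 values of named genes, 433 stayed within the limits set for them. For genes named across populations and genes reported whatever their ratio, those limits were the range of log2 ratios over the compared populations. That range can be wider than a counting interval, so these values were not compared with counting error. Of 126 gene counts, 80 stayed within 1.5 times. The cause was not tested for any value below, except that lower CPM minimums and no filter consider more genes. Counting every barcode adds the excluded and failed ones.

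Own clusters gave share ratios of 0.0103 for DEEx, 9.97 for OEE_IEE and 1.16 for class 3 (all reversed), 2.90 for class 1 and 0.00539 for class 2, and no value for AMB_dist and upper_IEE. Several of these clusters held almost only 1 library, so they do not hold the authors' populations. Cells at or above the 10th percentile of depth gave 0.834 for class 3. The planned use of automatic doublet calls moved nothing, since none were made.

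With a minimum of 10 CPM, genes higher and lower by 2-fold were 66 and 96 across populations, 100 and 335 over all cells, 410 and 553 in M_G1, 159 and 489 in S, 283 and 361 in G2_M, 513 and 605 in DEEx, 989 and 851 in OEE_IEE, 735 and 569 in OEE_2, and 823 and 609 in OSR. With no filter beyond 1 count in each library they were 74 and 105 across populations, 857 and 1480 in M_G1, 606 and 1342 in S, 856 and 1003 in G2_M, 835 and 928 in DEEx, 971 and 917 in OEE_IEE, 974 and 742 in OEE_2, and 1086 and 686 in OSR. Without mitochondrial and ribosomal protein genes in the totals, 20 were higher across populations, and 170 were lower in M_G1, 148 in S, 153 in DEEx, 272 in OEE_IEE and 144 in OSR. Leaving out genes of other sources left 23 lower across populations and 49 over all cells. Over all cells, DESeq2 size factors gave 67 higher, every barcode 81 higher and 226 lower, and medians within populations 52 lower. Of the 31 higher and 40 lower genes across populations, TMM kept 27 and 39, mean CPM per cell 27 and 33, doublets left out 26 and 37, and M_G1 left out 24 and 36.

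Counting every barcode reversed the log2 ratios of Lum (-0.015), Col1a1 (-1.24) and Pmaip1 (-0.46). Excluded barcodes held 1340 control and 332 injured Col1a1 UMIs, against 155 and 728 in retained cells. For Lum they held 1440 and 456, against 578 and 2719 in retained cells. The reversals of Lum and Col1a1 thus come with the added barcodes and do not speak to the ratios in retained cells. The G2/M list at 0.34 with a minimum of 50 CPM, and the Notch list at -0.20 there and -0.077 within populations, fell inside the random range. The progenitor list left that range upward, at 0.78 under either of these settings. With a minimum of 50 CPM the p53 target list also left it upward (0.48) and the stellate reticulum and outer epithelium list downward (-0.75, 3 genes).

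Ratios of G2/M positive cells over all cells were 1.496 at a thinned depth of 1000 UMIs, 1.34 with 1 UMI and 1.47 without thinning. In class 1 they were 0.983 at 1000 UMIs and 1.08 without thinning, and in class 3 they were 1.37 with 1 UMI and 1.47 without thinning. Ratios of S-phase positive cells over all cells were 1.59 at 1000 UMIs, 1.17 with 1 UMI, 1.68 with 3 UMIs and 1.22 without thinning. In class 1 these were 1.24, 1.08, 1.27 and 1.08, and in class 3 they were 1.08 with 1 UMI, 1.47 with 3 UMIs and 1.12 without thinning. Populations under 100 cells in either library had no gene ratios. Depth limits the comparisons with few UMIs: in OEE_IEE, 37 of 3067 genes simulated as unchanged passed the 2-fold limit by counting error alone.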

Other observations

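No test in this part was planned, and its genes were chosen after their values were seen. Sfrp5, Golga7b and Crtac1 lie next to one another on chromosome 19 (42197971 to 42431783, GRCm38), and all were higher in each of the 7 compared populations of the injured library. Golga7b had 32 control and 947 injured UMIs over all retained cells, a 13.4-fold higher CPM (9.42 to 19.7), with a median of 10.0-fold over populations. Sfrp5 was 4.38-fold and Crtac1 2.57-fold higher over all cells. The nearest measured genes on either side had ratios near 1, Zfyve27 with 1.08 (0.947 to 1.22) and R3hcc1l with 1.11 (0.894 to 1.40). Regulation, transcription running on from 1 gene into the next and the genotype of the pooled animals were not tested and stay open for these ratios.

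Erythroid genes summed to 3077 CPM (2088 UMIs) in control barcodes that failed the quality filter and to 7.29 CPM (4 UMIs) in injured ones. Immune genes summed to 25391 and 6653 CPM there. In retained cells the erythroid list stood at 21.7 and 1.19 CPM, and AMB_prox, with 67 control and 2 injured cells, held 84 of the 119 control UMIs of Hba-a1. By the authors' assignment, the share of G2_M cells closest to OEE_2 was higher in the injured library (3.29% and 12.7%, ratio 3.85, 1.87 to 7.92), while in S that share was 0.845% and 1.37% with an interval that held 1. Ribosome biogenesis genes had a median log2 ratio of 0.50 in class 1 and -0.03 in class 3, and the difference was not tested.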
